A study of Homo sapiens with 24 samples.

How the data were processed

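One-colour CodeLink whole human genome arrays were read for 18 T-HESC and 6 U-937 cultures, 1 sample per array, labelled with a single fluorescent dye and run with bacterial spike controls. The deposited values are intensity on a linear scale, background already subtracted and each array scaled by the authors so that its median is about 1; a few values are 0 or below and some cells are empty. The copy of the series text used here breaks off in mid-sentence, and what follows on missing details holds for that copy. The scanner software, the background method and the rule that emptied cells are not given in the sources used here. The sources used here state 10% serum in one place and 2% in another. The part of the series text used here gives no control medium for the T-HESC cultures without monocyte medium. Which replicate number stands for which passage (5, 7 and 9 for T-HESC, 7, 9 and 12 for U-937) is not given there either. Serum was removed on day 6 and monocyte medium added on day 7.

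The table holds 54359 probes. A probe took the gene symbol that the array annotation gave it where that was a single symbol (23472 probes, 23434 of them matched to a current gene by Entrez id and 0 symbols updated), while 905 probes with several symbols and 29982 with none stayed in the tests of probes but carry no gene name. Where a gene had several probes, the probe with the highest mean stood for it. Chromosome positions were not used here. All 24 arrays were used, and the highest correlation among the 276 pairs of arrays was 0.9891, with 0 pairs identical.

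Intensities were taken to log2, with values of 0 or below set as missing. The 2 cell lines were fitted separately with limma 3.58.1 in R 4.3.3 (lmFit, contrasts, and eBayes with an intensity trend): 6 groups of 3 arrays for T-HESC and 2 groups of 3 for U-937. Probes were tested when their mean log2 intensity reached the 40th percentile and each group had at least 2 values, which left 32479 probes (13751 genes) in T-HESC and 32437 (13520 genes) in U-937. P-values were adjusted by Benjamini and Hochberg over the probes, or over the genes, of a comparison, and a change was called at an adjusted p under 0.05. The 15 comparisons were monocyte medium in each of the 3 hormone states and averaged, the 3 hormone contrasts without and with monocyte medium and averaged, the interaction of monocyte medium with the hormone state, and T-HESC medium in U-937. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

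Groups, comparisons, 17 gene lists, 4 marker lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule named, per direction, the 12 genes with the largest called change in the averaged comparisons (moving the same way in every state) and in U-937 (with groups that did not overlap) and the 3 largest in the others, the 4 most changed called members of each list (2 where none was called), the 5 genes with the smallest interaction p, and ESR1, ESR2, PGR and NR3C1. A further gene that the rule names is not reported here. Genes named outside the rule are marked where they appear. Lists were tested against the other genes with camera at a preset correlation of 0.01, again with the correlation estimated, and adjusted over the lists of a comparison. The lists were inflammatory NF-kB targets, interferon-stimulated genes, chemokines and cytokines, matrix proteases and inhibitors, collagens and matrix, decidualization, estrogen receptor targets, glucocorticoid and progesterone receptor targets, proliferation, immediate early genes, cholesterol synthesis, hypoxia and glycolysis, amino acid starvation and unfolded protein response, TGF-beta targets, antigen presentation and complement, oxidative stress, and monocyte to macrophage differentiation, with markers of stromal, monocyte, epithelial and endothelial cells.

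Whether replicate numbers pair the samples was checked by correlating, across probes, each array's departure from its group mean with those of the other group. They were taken as paired when each correlation between arrays of the same number was above 0.1. This held for estradiol against vehicle without monocyte medium (0.343, 0.329 and 0.358) and with it (0.783, 0.372 and 0.753), for MPA with estradiol against both without monocyte medium and against vehicle with it and averaged, for monocyte medium in estradiol (0.197, 0.17 and 0.145), and for U-937 (0.151, 0.109 and 0.234). It did not hold for monocyte medium with MPA (0.136, 0.0656 and 0.113) or in vehicle (0.12, 0.0856 and 0.154), for the average over hormone states, for MPA with estradiol against estradiol with monocyte medium or averaged, or for the interaction. For monocyte medium with MPA and in vehicle all 6 arrays still correlated best with the array of their own number. Only the threshold failed there, so these samples may be paired as well. A fit with the replicate number as a block was planned as an alternative for every comparison.

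Array sets were read from the cells left empty, after the data were seen. The number of probes empty on all arrays of 1 set and on no other array was 45, 125 and 256 in the first set, the second and the third, and on the arrays of the other sets these probes lay at a median percentile of 41.2, 51.4 and 48.5. An array had 95 to 183 empty cells in the first set, 167 to 214 in the second and 305 to 355 in the third. The 20th percentile of intensity, the low end of the signal relative to the array median, was 0.257 to 0.356, 0.22 to 0.237 and 0.221 to 0.257 in the 3 sets.

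The limma and camera tests were run on simulated data, for 31804 T-HESC and 32254 U-937 probes with a value on every array. Values were drawn as independent normal noise around the mean of each probe, and 200 probes were given a known change. Changes of 1 on the log2 scale were called in 60% of probes for monocyte medium with MPA, 62% for MPA with estradiol against vehicle without monocyte medium, 63% for estradiol without monocyte medium, 49% in U-937 and 34% for the interaction. Changes of 2 were called in 84%, 88%, 85%, 90% and 79%. False calls made up 2.17% to 7.77% of the calls. Of 14 shifted lists camera called 14, and 1 of 266 others. The simulation held no array sets, no replicate pairing, no deviating array and no correlation between genes. These rates therefore need not hold for the real arrays and lists.

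The alternatives planned were quantile normalization, median centring, no intensity filter, a filter at the 60th percentile, an offset added before log2 (the 20th percentile, 0.28 in T-HESC and 0.226 in U-937), eBayes without the trend, array weights, the replicate block, only the arrays of the groups compared, leaving out each array, the mean over the probes of a gene, and camera with an estimated correlation. Chosen after seeing the data were the array set as a block, a fit of the first array set alone, the interaction inside array sets, the overlap of both cell lines with the effect inside the first set, and U-937 without control replicate 3. Other splits of the arrays into groups of the same sizes were counted with the same fit, all 10 for 3 arrays against 3 and 100 drawn with seed 1 otherwise.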

Results

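RNA was measured on 24 one-colour CodeLink whole human genome arrays, each hybridised with RNA from a single culture. T-HESC, a telomerase-immortalised human endometrial stromal cell line, gave 18 arrays in 6 groups of 3. The cells received vehicle, estradiol (10 nM) or estradiol with the progestin medroxyprogesterone acetate (100 nM, called MPA here) for 8 days, each without or with medium conditioned by U-937 monocytes (called monocyte medium) for the last 24 hours. U-937, a human monocytic line, gave 6 arrays: 3 cultures in medium conditioned by T-HESC and 3 in control medium that was not conditioned. Per the series text, each experiment was repeated with 3 passages of its cell line, so p-values measure the spread between cultures of 1 line, and the number of arrays limits the precision. Values are intensities scaled so that the median probe of an array is about 1. The SE is given for part of the log2 changes, a value after ± is the SD of an intensity, and n = 3 per group.

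The stromal markers had a median intensity of 86.9 to 116 across the T-HESC groups and 0.32 in control U-937. The monocyte markers had a median of 45.6 in control U-937 and 0.509 to 0.732 across the T-HESC groups. Endothelial markers lay between 0.683 and 0.906 in T-HESC, and epithelial markers between 1.29 and 1.56 in the 4 groups of the first array set described next, 2.06 in vehicle with monocyte medium and 2.46 in estradiol with monocyte medium.

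The probes left empty in the table parted the arrays into 3 sets. The first held the 12 arrays of vehicle, estradiol, estradiol with MPA, and estradiol with MPA and monocyte medium. The second held the 6 arrays of vehicle or estradiol with monocyte medium, and the third the 6 U-937 arrays. Comparisons inside a set are given first. Monocyte medium in vehicle and in estradiol coincides with the array set, and so does MPA in the presence of monocyte medium. Averages over hormone states or media hold these contrasts in part, except for estradiol against vehicle, which each set holds in full.

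**Figure D1:**
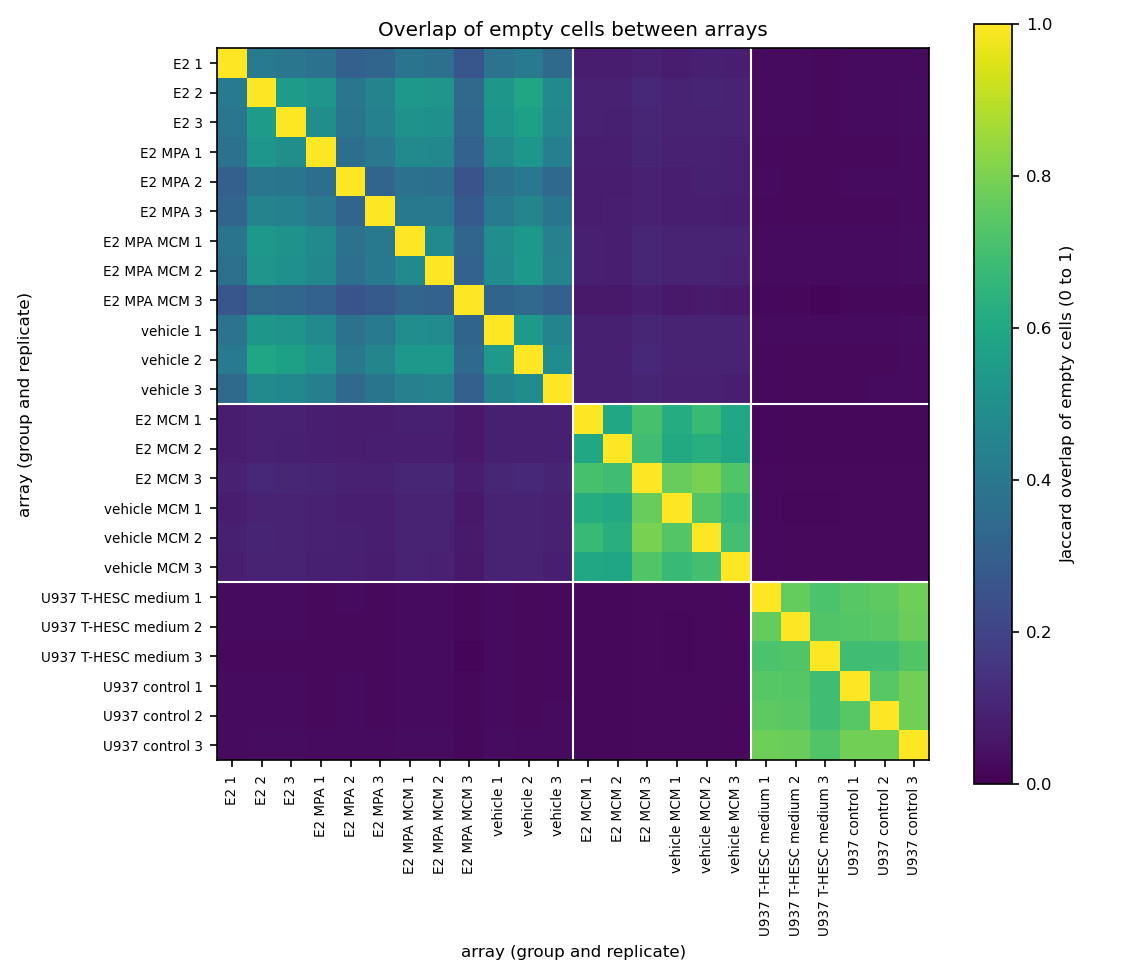
Share of empty probes that each pair of the 24 arrays had in common (Jaccard index, colour scale), arrays ordered by array set and the sets boxed. Within sets the index ran from 0.26 to 0.799 and between sets from 0.0189 to 0.112.

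The first comparison asked how T-HESC without monocyte medium responded to the progestin given with estradiol. ZBTB16 (probe 450103), a zinc-finger transcription factor induced by progestins and glucocorticoids, rose against vehicle (log2 change 5.58, SE 0.326, adjusted p = 1.78e-07), from an intensity of 0.474 ± 0.273 to 20.8 ± 3.44 (n = 3). The complement component C6 rose as well (3.91, SE 0.473, adjusted p = 0.000459). The vehicle intensities of ZBTB16 and C6 all lay below the median of their arrays, at the low end of the signal, so the size of their ratios is uncertain: with an offset added to the intensities the log2 changes were 4.85 and 3.03. HSD11B1, which turns cortisone into cortisol, rose 5.34-fold (2.42, SE 0.4, adjusted p = 0.00572). The interstitial collagenase MMP1 (probe 241106) fell from 21.6 ± 7.82 to 3.01 ± 0.422 (log2 change -2.79, SE 0.361, adjusted p = 0.000688, n = 3), and so did ENC1, an actin-binding Kelch protein, from 9.74 ± 1.5 to 1.98 ± 0.032 (-2.29, SE 0.269, adjusted p = 0.000403, n = 3). IGFBP3, which binds insulin-like growth factors, fell by 1.78 on the log2 scale (SE 0.208, adjusted p = 0.000392), while IGF1, a growth factor it binds, rose by 1.83 (SE 0.216, adjusted p = 0.000403). CORIN (probe 233053), a membrane protease that activates natriuretic peptides, rose from 4.25 ± 0.438 to 50.8 ± 5.27 (3.58, adjusted p = 1.28e-07, n = 3). CORIN was chosen here after its values were seen, although the naming rule selected it against estradiol alone.

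Against estradiol alone the same direction was found for ZBTB16 (5.72, SE 0.326, adjusted p = 8.32e-08, 4.95 with the offset), C6 (5.20, SE 0.473, adjusted p = 2.25e-05, 3.62 with the offset), CORIN (3.65, SE 0.195, adjusted p = 4.87e-08), HSD11B1 (2.69, adjusted p = 0.00282), IGF1 (1.82, adjusted p = 0.000384), MMP1 (-2.49, adjusted p = 0.00244) and IGFBP3 (-1.85, adjusted p = 0.00023). FRZB, a secreted WNT antagonist, fell from 6.67 ± 3.56 to 1.26 ± 0.213 (-2.28, SE 0.309, adjusted p = 0.00147, n = 3). The vehicle and estradiol comparisons share the arrays with MPA.

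**Figure D2:**
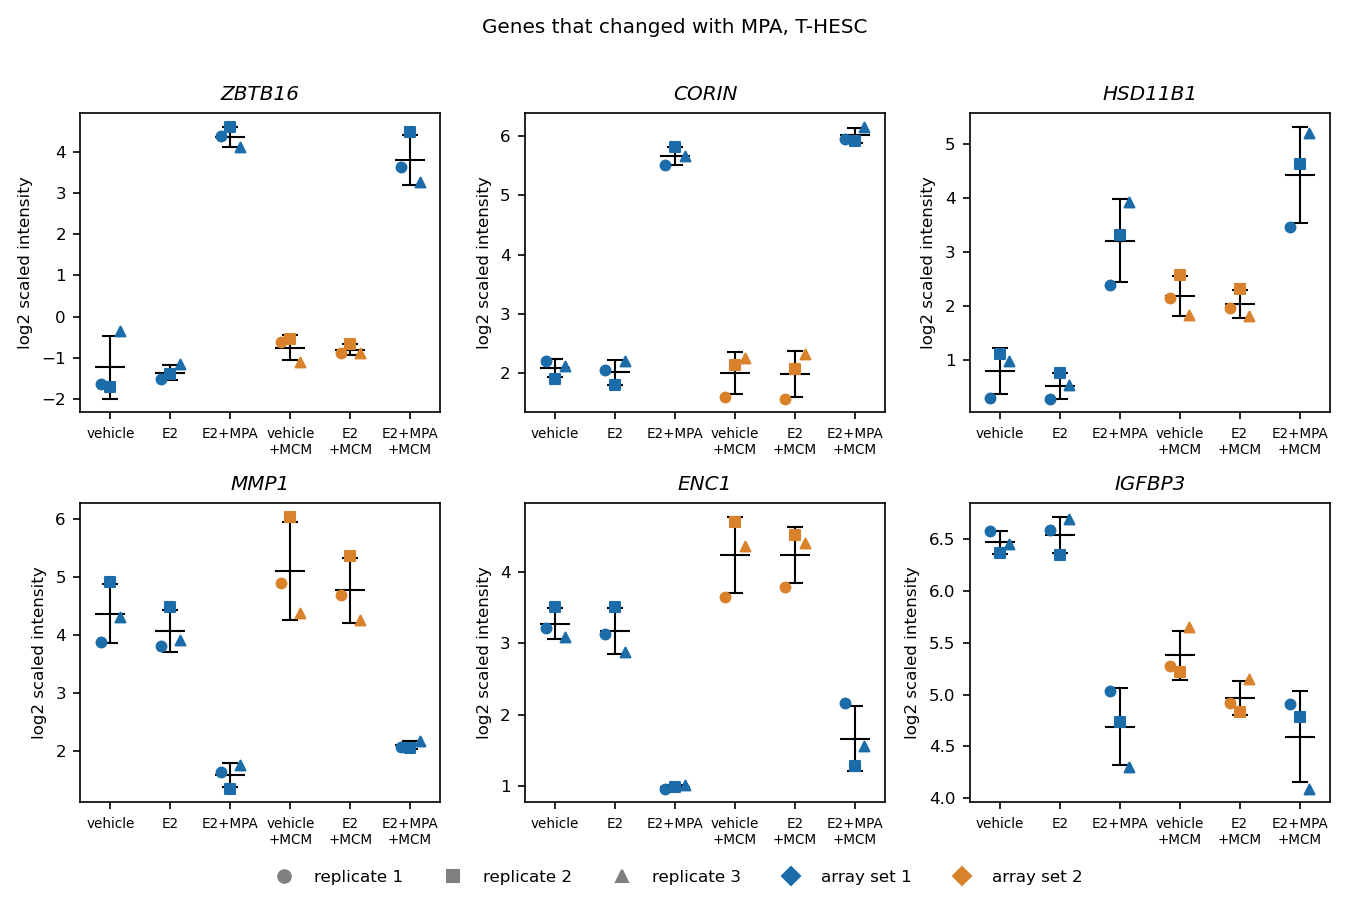
Intensity (log2 axis) of ZBTB16, CORIN, HSD11B1, MMP1, ENC1 and IGFBP3 on each of the 18 T-HESC arrays by group, with markers for the replicate number, colours for the array set and bars for the mean and SD of log2 intensity. Without monocyte medium ZBTB16 averaged 0.474 in vehicle, 0.393 in estradiol and 20.8 with MPA.

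Among the gene lists, only the glucocorticoid and progesterone receptor targets passed with both forms of the camera test. Of 18 tested against vehicle, 4 rose (with ZBTB16, HSD11B1 and the glutamine synthetase gene GLUL among them), 0 fell and 14 did not pass, and adjusted over the list alone 7 rose. The list ranked above the other genes (adjusted p = 2.7e-07, and 0.00218 with an estimated correlation). Against estradiol 4 rose, 8 when adjusted over the list alone (adjusted p = 6.6e-10, and 5.18e-04 with an estimated correlation). Of 26 collagens and matrix genes against vehicle, 1 rose and 3 fell, 4 and 6 when adjusted over the list alone, and the proteoglycan LUM was among those that fell (456 ± 48.9 to 229 ± 12.8, log2 change -0.99, adjusted p = 0.00189, n = 3). Among 22 inflammatory NF-kB targets 1 rose and 1 fell. The first was TNFAIP3, which dampens NF-kB signalling (1.89, SE 0.241, adjusted p = 0.00065). MMP1 was the only called member of 23 matrix proteases and inhibitors, of which 2 fell when adjusted over the list alone.

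The other lists gave few calls against vehicle. Of 25 interferon-stimulated genes 1 fell (4 when adjusted over the list alone), of 21 decidualization genes 1 fell (1 rose and 3 fell when adjusted over the list alone), and of 17 estrogen receptor targets 1 rose and 1 fell (1 and 3 when adjusted over the list alone). Hypoxia and glycolysis genes had 1 lower call of 19 and the TGF-beta targets 1 in each direction of 17. None of the 18 chemokines and cytokines, 31 proliferation genes, 16 immediate early genes, 18 cholesterol synthesis genes, 15 antigen presentation genes, 11 oxidative stress genes or 10 macrophage differentiation genes was called by limma. Adjusted over the list alone, 1 chemokine, 3 immediate early and 1 oxidative stress gene were lower. As a list, the 21 amino acid starvation and unfolded protein response genes ranked lower (1 called lower, adjusted p = 0.01, and 0.883 with an estimated correlation), and so did the proliferation genes (adjusted p = 0.0453, and 0.883 with an estimated correlation). Against estradiol the immediate early genes ranked lower (0 called, 5 lower when adjusted over the list alone, adjusted p = 0.0172, and 0.594 with an estimated correlation), as did the unfolded protein response list (adjusted p = 0.027, and 0.741 with an estimated correlation). In a fit of the first array set alone, chosen after seeing the data, these calls were lost against estradiol for the immediate early genes (adjusted p = 0.0515) and the unfolded protein response list (adjusted p = 0.0517) and against vehicle for the proliferation genes (adjusted p = 0.0746), while the unfolded protein response list still passed against vehicle (adjusted p = 0.0374, and 0.935 with an estimated correlation). With all T-HESC arrays in the fit and the preset correlation, the proliferation list (adjusted p = 0.0534) and the interferon list (adjusted p = 0.0581) passed against estradiol only under alternatives: with a replicate block, each at 0.024, and after quantile normalization, each at 0.0485. Stromal markers had 1 higher and 3 lower calls of 13, and 0 calls were made among 10 monocyte, 9 epithelial and 5 endothelial markers.

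Of 32479 probes tested, 420 were called against vehicle (230 higher, 190 lower, with 4449 at an unadjusted p under 0.05) and 238 against estradiol (144 higher, 94 lower, with 2873 at an unadjusted p under 0.05). In genes these were 105 higher and 103 lower, and 77 higher and 53 lower. With the replicate numbers, which paired these samples, as a block, 1216 (564 higher, 652 lower) and 634 probes were called. After quantile normalization the share of higher calls against vehicle was 68.41% in place of 54.76%. The call of the glucocorticoid receptor gene NR3C1 (-0.56, adjusted p = 0.0479) was lost under several alternatives, and ESR1 (adjusted p = 0.282), ESR2 (adjusted p = 0.137) and PGR (adjusted p = 0.584) were not called. The count against vehicle was 228, 230 and 164 without estradiol with MPA replicates 1, 2 and 3, and 236 without vehicle replicate 2. Against estradiol it was 136, 135 and 143 without estradiol replicates 1, 2 and 3, and 153, 116 and 101 without estradiol with MPA replicates 1, 2 and 3.

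Estradiol alone was compared with vehicle to find the response of T-HESC to estrogen. Among the estrogen receptor targets, 0 of 17 were called without monocyte medium or averaged over both media, and ESR1 (0.00), ESR2 (0.07), NR3C1 (0.02) and PGR (0.11) each had an adjusted p of 1 in the average. Without monocyte medium limma called 2 probes of 32479 (1226 at an unadjusted p under 0.05). The long non-coding RNA gene MHENCR was higher (log2 change 2.70, SE 0.295, adjusted p = 0.00302), at 0.968 ± 0.0719 against 0.15 ± 0.0239 (n = 3), and with an offset added to the intensities it was not called (1.54, adjusted p = 0.0725). Probe 158036, which has no gene symbol and was chosen after its values were seen, was lower (-3.38, SE 0.37, adjusted p = 0.00474). Its intensity, 0.0226 ± 0.0288 against 0.249 ± 0.293 (n = 3), lay near the bottom of the scale. With the replicate block 4 probes were called, and after quantile normalization 3, of which 66.67% were higher in place of 50%. The count was 1 without estradiol replicate 1 or 3, 4 without vehicle replicate 1 and 6 without vehicle replicate 3. With monocyte medium limma called 0 probes (1580 at an unadjusted p under 0.05) and averaged over both media 0 (787 at an unadjusted p under 0.05). With the block these counts were 3 and 0, and without vehicle replicate 2 the averaged count was 1.

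In that average the oxidative stress list, targets of the transcription factor NRF2, ranked lower under estradiol although 0 of its 11 genes were called (adjusted p = 0.0189, and 0.84 with an estimated correlation). With monocyte medium alone it did not pass (adjusted p = 0.096) except with the replicate block (adjusted p = 0.0354) and after quantile normalization (adjusted p = 0.0401).

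**Figure D3:**
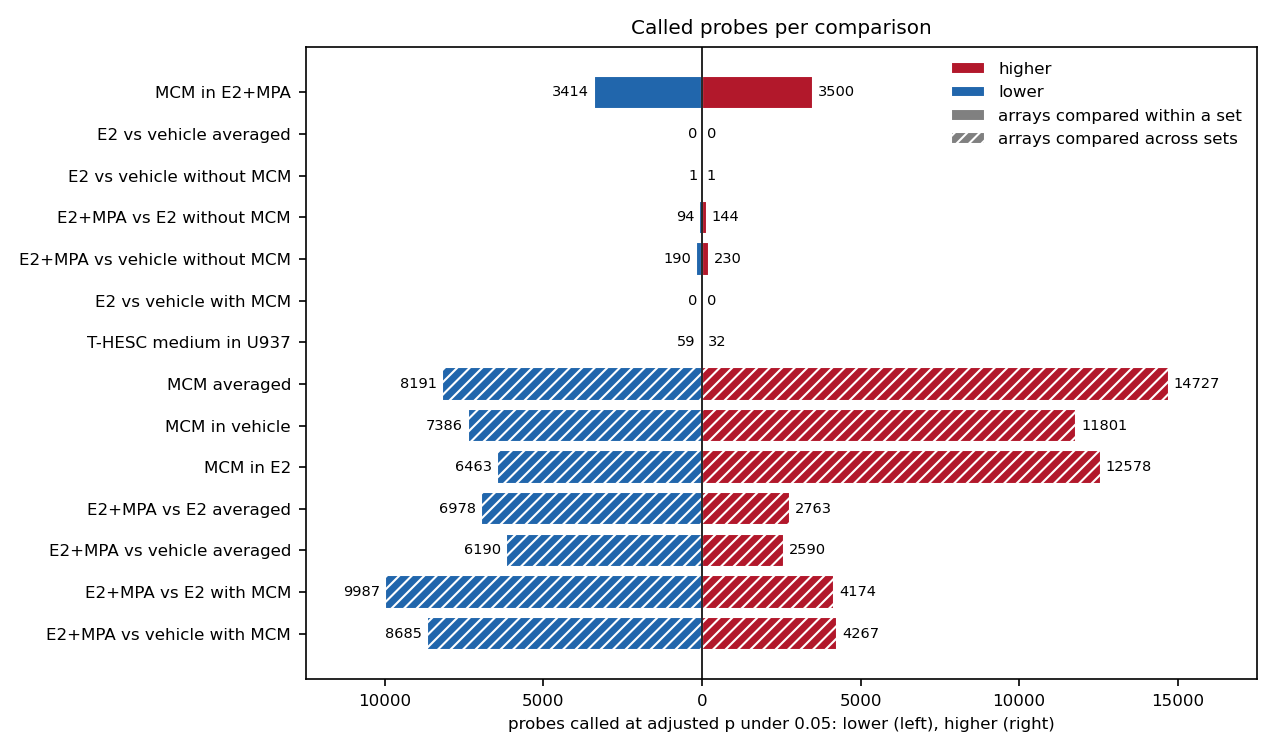
Number of probes called per comparison, higher to the right and lower to the left, with hatching where the comparison crosses array sets. Inside a set the counts were 6914 for monocyte medium with MPA, 420 and 238 for MPA without monocyte medium, 91 in U-937, and 2 and 0 for estradiol without and with monocyte medium. Averaged over arrays of 2 sets, estradiol gave 0.

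The next comparison asked what monocyte medium changed in T-HESC, first in cells given estradiol with MPA, where both groups lay in the first array set. Among the largest called increases were EAF2, an RNA polymerase elongation factor (3.83, SE 0.864, adjusted p = 0.00576, and 3.02 with an offset, since it started near the low end of the signal), and LPCAT2 (probe 451019), which makes platelet-activating factor (8.56-fold, 3.10, SE 0.338, adjusted p = 2.12e-05). GDF15 (probe 395034), a stress-induced cytokine of the TGF-beta family, rose from 20.8 ± 4.76 to 165 ± 61.4 (2.95, SE 0.476, adjusted p = 0.000554, n = 3). PRMT6 (probe 37027), an arginine methyltransferase, fell from 21.6 ± 3.92 to 1.22 ± 0.355 (-4.17, SE 0.667, adjusted p = 0.000518, n = 3), and the adhesion receptor ADGRB3 fell from 20.6 ± 3.75 to 1.42 ± 0.417 (-3.89, SE 0.241, adjusted p = 2.43e-07, n = 3). SOD2 (probe 397021), the mitochondrial superoxide dismutase induced by inflammatory cytokines, rose from 6.39 ± 0.231 to 42.6 ± 4.82 (2.73, SE 0.224, adjusted p = 2.13e-06, n = 3). The chemokine CXCL12 (probe 165086) fell from 73.1 ± 16.1 to 15.4 ± 6.03 (-2.31, SE 0.31, adjusted p = 0.000129, n = 3), and IGF1 fell from 13.5 ± 3.63 to 2.01 ± 0.484 (-2.74, SE 0.216, adjusted p = 1.56e-06, n = 3).

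Of 16 immediate early genes of the serum and growth factor response, 7 rose and 0 fell, also when adjusted over the list alone. CCN1, a matrix signalling protein (2.30, SE 0.267, adjusted p = 3.7e-05), the stress transcription factor ATF3 (1.98, SE 0.394, adjusted p = 0.00254) and PHLDA1 (1.25, adjusted p = 0.00616) were among them. The list ranked higher (adjusted p = 0.00441, and 0.753 with an estimated correlation). Of 21 amino acid starvation and unfolded protein response genes, 6 rose and 0 fell, 9 and 0 when adjusted over the list alone, with CTH, which makes cysteine (2.22, SE 0.367, adjusted p = 0.000672), and the glycoprotein hormone STC2 (2.33, SE 0.472, adjusted p = 0.00288) among them. This list too ranked higher (adjusted p = 0.00258, and 0.98 with an estimated correlation).

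No other list passed the camera test in this comparison. Interferon-stimulated genes gave 2 higher and 6 lower calls of 25, with SAMD9 (-2.55, adjusted p = 0.00112) and XAF1 (-1.65, adjusted p = 0.00419) among the lower. The 22 NF-kB targets gave 2 higher calls, SOD2 and the NF-kB subunit RELB (2.08, SE 0.322, adjusted p = 0.000413), and TRAF1 lower (-1.21, adjusted p = 0.00117). Matrix genes gave 3 in each direction of 26, with the collagen cross-linking enzyme LOX higher (1.17, SE 0.143, adjusted p = 5.88e-05), and matrix proteases and inhibitors 5 higher and 2 lower of 23. Glucocorticoid and progesterone receptor targets gave 4 higher and 2 lower of 18, with the transcription factor CEBPD higher (2.54, adjusted p = 8.82e-05) and the caveolar protein CAVIN2 lower (-2.65, adjusted p = 1.93e-05). Estrogen receptor targets gave 4 higher and 3 lower of 17. CXCL12 was the only call among 18 chemokines and cytokines. A fit of the first array set alone, chosen after seeing the data, called CXCL8 higher and CXCL12 lower of 16. Antigen presentation genes gave 1 in each direction of 15, the peptide transporter TAP1 higher (1.49, SE 0.23, adjusted p = 0.000396) and NLRC5, an activator of class I genes, lower (-1.32, adjusted p = 0.00596). Higher and lower calls were 2 and 2 of 19 hypoxia genes, 1 and 3 of 31 proliferation genes, 1 and 1 of 18 cholesterol synthesis genes, 1 and 1 of 11 oxidative stress genes, 1 and 0 of 21 decidualization genes, 1 and 0 of 10 macrophage differentiation genes and 0 and 0 of 17 TGF-beta targets. In the fit of the first set alone the cholesterol synthesis genes gave 6 higher and 1 lower of 18. The list did not pass there (camera, adjusted p = 0.0732, and 0.963 with an estimated correlation). Adjusted over the list alone the proliferation and decidualization lists had 0 calls, the hypoxia genes 3 higher and 2 lower, the oxidative stress genes 2 higher and 1 lower, the receptor targets of glucocorticoids and progesterone 5 higher and 2 lower and those of estrogen 4 in each direction. The marker lists gave 3 higher and 1 lower of 13 stromal, 1 higher of 10 monocyte (0 when adjusted over the list alone), 1 lower of 9 epithelial and 0 of 5 endothelial markers.

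Of 32479 probes, 6914 (21.29%) were called, 3500 higher and 3414 lower. Among the 2547 that changed at least 2-fold, 842 were higher and 1705 lower. In genes, 1602 rose and 1870 fell. The count was 4491 and 4357 without estradiol with MPA replicates 1 and 2, and 4498 without replicate 3 of the group with monocyte medium. ESR1, ESR2, PGR and NR3C1 were not called.

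**Figure D4:**
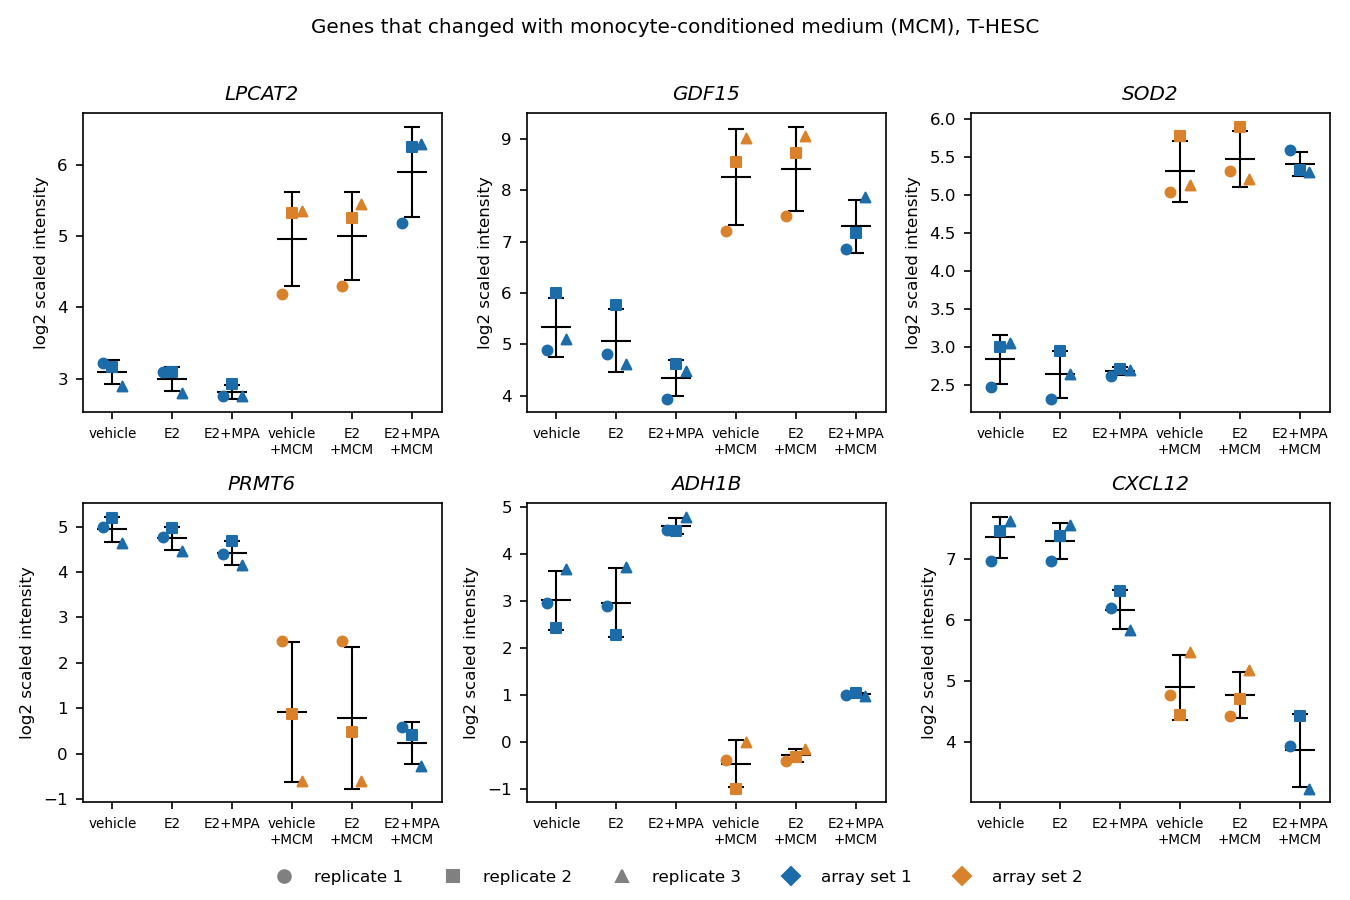
Intensity (log2 axis) of LPCAT2, GDF15, SOD2, PRMT6, ADH1B and CXCL12 on each of the 18 T-HESC arrays by group, with markers for the replicate number, colours for the array set and bars for the mean and SD of log2 intensity. With estradiol and MPA, SOD2 averaged 6.39 without and 42.6 with monocyte medium, and CXCL12 73.1 and 15.4.

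Monocyte medium was also compared in vehicle, in estradiol and averaged over the 3 hormone states, which crosses array sets. Beside each averaged change of a gene stands the value with the array set as a block, an alternative chosen after seeing the data. Since the second set holds only monocyte medium without MPA, that value is the effect of monocyte medium with MPA alone. It repeats the result inside the first set and does not check the effect in vehicle or estradiol. GDF15 rose by 3.07 on the log2 scale (adjusted p = 8.7e-08, 2.95 with the block), SOD2 by 2.68 (adjusted p = 1.99e-10, 2.73 with the block) and USP53, a tight-junction protein, by 3.44 (adjusted p = 8.21e-11, 2.53 with the block). ACACB, which controls fatty acid oxidation (-4.29, -3.62 with the block), the alcohol dehydrogenase ADH1B (-3.44, adjusted p = 6.81e-10, -3.59 with the block, its size uncertain in the second set, where it ended at about the array median or below) and CXCL12 (-2.43, adjusted p = 1.17e-08, -2.31 with the block) fell. The phosphatase DUSP5 rose by 3.93 (adjusted p = 4.27e-08), against 2.21 with the block. Other large changes lost their call with the block: the hormone STC1 (3.47, against 0.80 with adjusted p = 0.598), the keratin KRT34 (3.72, against 1.51 with adjusted p = 0.0914) and the neutrophil chemokine CXCL8 (2.96, against 1.03 with adjusted p = 0.186). CXCL8 was nevertheless called higher with MPA in the fit of the first array set alone. NR3C1 fell by 0.91 (adjusted p = 4.54e-08), which was -0.35 with the block (adjusted p = 0.0843), and ESR2, which rose by 0.53 (adjusted p = 3.77e-07), had the opposite sign with the block (-0.15). ESR1 (adjusted p = 0.292) and PGR (adjusted p = 0.896) were not called.

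In the average 12 of the 16 immediate early genes rose and 0 fell, and this list came nearest to passing (adjusted p = 0.0553, 0.0111 without the intensity filter and 0.03 after quantile normalization). Of the NF-kB targets 13 rose and 2 fell, of the chemokines and cytokines 12 rose and 2 fell, and of the cholesterol synthesis genes 12 rose and 2 fell. Of the interferon-stimulated genes 4 rose and 12 fell, and of the proliferation genes 5 rose and 19 fell. No list passed the camera test in these comparisons. These counts are not free of the array set. Inside the first set, with MPA, the calls were 0 higher and 1 lower for the chemokines and cytokines, 1 and 1 for cholesterol synthesis and 2 and 1 for the NF-kB targets. They were 2 and 6 for the interferon-stimulated genes, 1 and 3 for proliferation and 7 and 0 for the immediate early genes. Fewer arrays were compared there, which alone lowers the counts: simulated log2 changes of 1 were called in 60% of probes, against 91% in the average. A fit of the first set alone, chosen after seeing the data, gave 1 and 1, 6 and 1, 3 and 2, 2 and 6, 2 and 4, and 7 and 0 in the same order. Monocyte markers rose in 6 of 10 and epithelial markers in 4 of 9, with 2 lower. Over all 13751 genes of the average 5496 rose and 4437 fell. The median intensity of all 19 monocyte markers did not rise with monocyte medium: 0.732 and 0.618 in vehicle, 0.613 and 0.509 in estradiol, and 0.58 and 0.57 with MPA, below the array median.

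The number of called probes was 22918 in the average (14727 higher, 8191 lower), 19187 in vehicle (11801 higher, 7386 lower) and 19041 in estradiol (12578 higher, 6463 lower). With the array set as a block the averaged count was 6928 (3431 higher, 3497 lower). The median log2 change of all tested probes was 0.27 in estradiol, 0.15 after quantile normalization. In 547 of 10355 genes of the average with called probes, probes were called in opposite directions. The 10355 include genes with only 1 called probe, so the share among genes with several is higher. Across 805 genes with 2 bright probes, Pearson's r between the probes of a gene was 0.225 for the effect in vehicle and 0.24 in estradiol. With MPA it was 0.411. Between vehicle and estradiol, 10323 probes were higher in both (4570.1 if independent), 5816 lower in both (1469.7) and 3 opposite. Between vehicle and estradiol with MPA these numbers were 1880 (1271.7), 2649 (776.37) and 566. These effects share no arrays but come from 1 cell line. Those in vehicle and in estradiol both hold the same difference between the first and the second array set, which by itself would raise their overlap above the independent numbers.

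MPA with estradiol was compared in the presence of monocyte medium and averaged over both media, again across array sets. With the array set as a block the value largely repeats the contrast without monocyte medium, so it does not check the effect with that medium. In the average against vehicle ZBTB16 rose by 5.06 (SE 0.23, adjusted p = 2.65e-09, 5.60 with the array set as a block), CORIN by 3.80 (adjusted p = 2.42e-10, 3.60 with the block), INHBB, a subunit of activin and inhibin, by 2.86 (adjusted p = 1.17e-08, 3.11 with the block) and the glucocorticoid-induced TSC22D3 by 2.54 (adjusted p = 5.31e-05, 1.91 with the block). MMP1 fell by 2.90 (adjusted p = 2.42e-06, -2.80 with the block). STC1 (-2.87) lost its call with the block (-0.87, adjusted p = 0.777), as did ESR1 (-1.85, adjusted p = 0.00054, against -1.12 with adjusted p = 0.223). ESR2, called lower (-0.20, adjusted p = 0.0355), had the opposite sign with the block (0.31).

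Among the receptor targets of glucocorticoids and progesterone 9 of 18 rose and 0 fell against vehicle (9 and 1 when adjusted over the list alone), and the list ranked higher (adjusted p = 1.56e-04, and 0.0162 with an estimated correlation). Against estradiol the counts were 9 and 0 (adjusted p = 3.04e-05, and 0.00908 with an estimated correlation). With monocyte medium alone this list passed against estradiol (adjusted p = 0.0243) and vehicle (adjusted p = 0.0338), though not with an estimated correlation (0.086 and 0.166). Chemokines and cytokines ranked lower in the average against vehicle (0 higher and 7 lower of 18, adjusted p = 0.0209, and 0.0979 with an estimated correlation) and against estradiol (0 and 7, adjusted p = 0.0137, and 0.061 with an estimated correlation), and so they did with monocyte medium alone (0 and 10, adjusted p = 0.0338, and 0.166 with an estimated correlation, against vehicle, and 0 and 12, adjusted p = 0.0243, and 0.086 with an estimated correlation, against estradiol). None of these chemokine calls held without the intensity filter. Inside the first array set, without monocyte medium, the chemokine list did not pass against vehicle (adjusted p = 0.357) or estradiol (adjusted p = 0.196) in the fit of that set alone. In each of these 4 comparisons 4 or 5 of the 10 monocyte markers were called lower, beside 2448 to 3660 of all 13751 genes. Immediate early genes (0 and 8, adjusted p = 0.0327, and 0.643 with an estimated correlation) and oxidative stress genes (0 and 5, adjusted p = 0.0209, and 0.73 with an estimated correlation) ranked lower in the average against vehicle, and the latter also with monocyte medium alone (1 and 7, adjusted p = 0.0338, and 0.719 with an estimated correlation).

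Against vehicle 8780 probes were called in the average and 12952 with monocyte medium, and against estradiol 9741 and 14161. With the array set as a block the averaged counts were 434 and 379. The share of higher calls was 29.5% and 32.94% against vehicle and 28.36% and 29.48% against estradiol, and after quantile normalization 48.85%, 44.74%, 46.01% and 43.46%. The median of all probes against estradiol with monocyte medium was -0.18, and -0.07 after quantile normalization.

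In U-937 the question was the response to T-HESC medium. FN1 (probe 65078), the matrix protein fibronectin, rose from 0.257 ± 0.0849 to 3.46 ± 0.278 (log2 change 3.80, SE 0.242, adjusted p = 0.000881, n = 3). Its control intensities lay at about the 20th percentile of their arrays, so the size of the ratio is uncertain, and with an offset the log2 change was 2.94. LTBP1 (probe 481093), which stores latent TGF-beta, rose 3.70-fold (1.89, SE 0.134, adjusted p = 0.00153), from 1.42 ± 0.105 to 5.25 ± 0.58 (n = 3). Both passed under every alternative that tested them, each left-out array included. S100A8, a myeloid calcium-binding protein, rose from 1.38 ± 0.787 to 5.45 ± 0.817 (2.12, SE 0.323, adjusted p = 0.0473, n = 3), with an adjusted p from 2.44e-07 to 0.277 when 1 array was left out and 0.0513 after quantile normalization. APOC2, a lipoprotein lipase cofactor, rose from 13.3 ± 1.56 to 35.6 ± 0.925 (1.42, adjusted p = 0.00769, n = 3), with a leave-one-out range from 9.4e-07 to 0.146, and the water channel AQP9 rose by 1.54 (adjusted p = 0.00638), with a range from 8.24e-06 to 0.115. CEACAM6, a cell adhesion protein of granulocytes, fell from 2.69 ± 0.256 to 0.68 ± 0.148 (4.01-fold, SE of log2 0.184, a log2 change of -1.70 with the offset since it ended at the low end of the signal, adjusted p = 0.00638, n = 3) and missed the threshold only without replicate 3 in T-HESC medium (adjusted p = 0.0767). NOP56, a nucleolar ribosome assembly factor, fell from 104 ± 5.03 to 46.3 ± 5.38 (-1.17, adjusted p = 0.0169, n = 3), with a range from 1.12e-05 to 0.194. Without the intensity trend S100A8 (adjusted p = 0.1) and NOP56 (adjusted p = 0.0574) were not called. MMP1 was not called (2.25, SE 0.644, adjusted p = 0.118, 19 ± 2.89 against 6.35 ± 7.44, n = 3) unless control replicate 3 was left out (3.21, adjusted p = 1.77e-08).

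**Figure D5:**
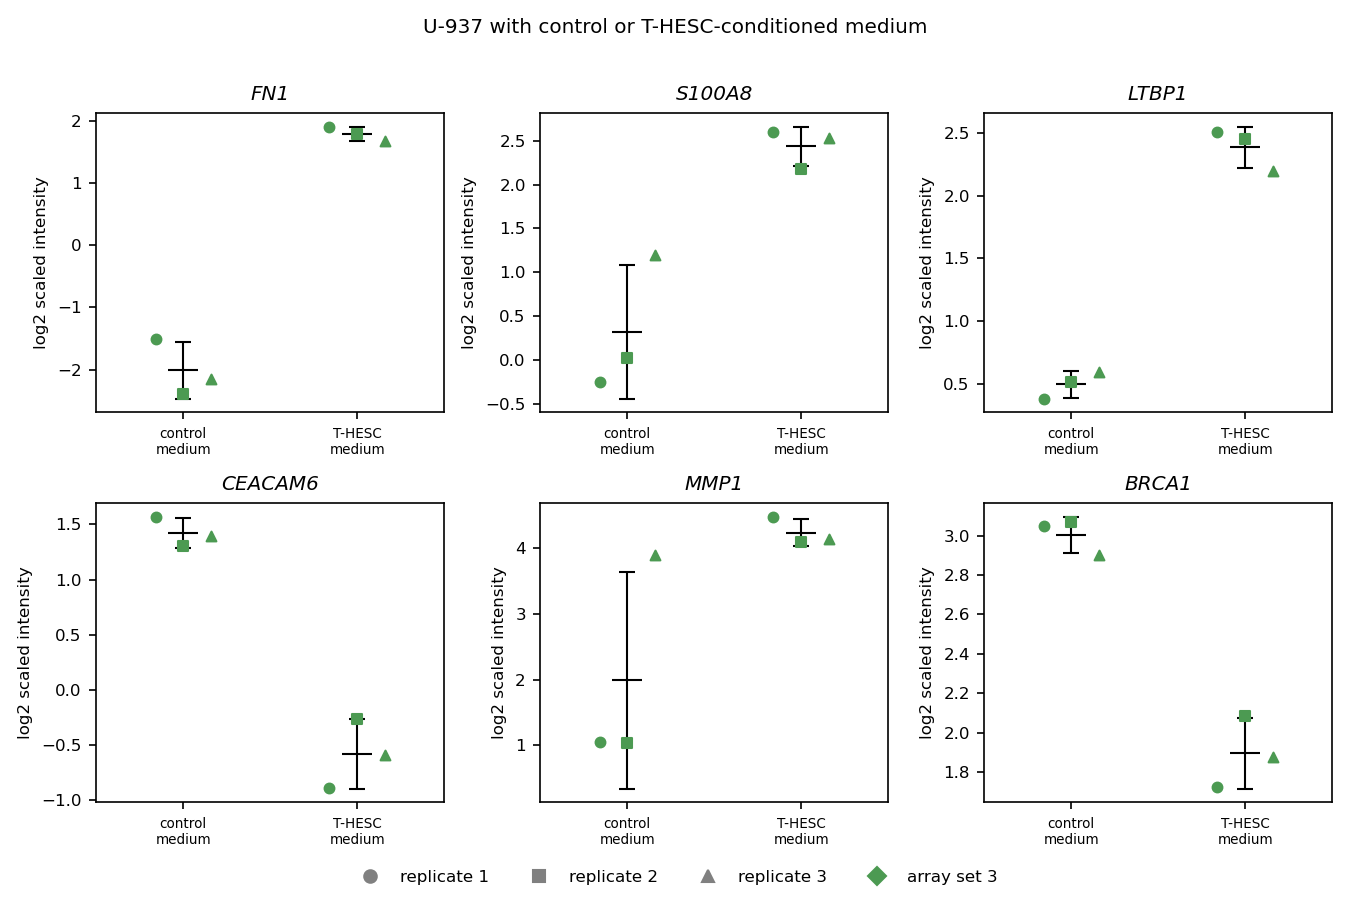
Intensity (log2 axis) of FN1, S100A8, LTBP1, CEACAM6, MMP1 and BRCA1 on each of the 6 U-937 arrays, control medium against T-HESC medium, with markers for the replicate number and bars for the mean and SD of log2 intensity. FN1 averaged 0.257 in control medium and 3.46 in T-HESC medium.

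Of 19 genes of monocyte to macrophage differentiation, 1 (S100A8) rose and 0 fell, 5 and 2 when adjusted over the list alone, and the list ranked higher (adjusted p = 0.00185, and 0.274 with an estimated correlation). The monocyte markers had a median intensity of 34.7 in T-HESC medium and 45.6 in control medium, with 0 of 18 called and 5 lower when adjusted over the list alone. FN1 was the only call of 15 matrix genes, and SKIL, a repressor of SMAD proteins (1.65, adjusted p = 0.0238), the only one of 11 TGF-beta targets. SKIL was not called when any array but control replicate 3 was left out (adjusted p from 0.106 to 0.244) or without the intensity trend (adjusted p = 0.0642). The other 14 lists had 0 genes called by limma and did not pass: among 32 proliferation genes 9 were lower when adjusted over the list alone (adjusted p of the list 0.0568, and 0.0165 without the intensity filter). Stromal, epithelial and endothelial markers were not called. Without control replicate 3 more of these lists gave calls: the macrophage list (6 higher and 4 lower, adjusted p = 5.17e-04), the oxidative stress genes (4 and 0, adjusted p = 0.00458) and the chemokines and cytokines (5 and 3, adjusted p = 0.0138) ranked higher, each at 0.616 with an estimated correlation. Higher members of the macrophage list were then S100A8, CD163, CD36, HLA-DRA, LYZ and VSIG4, and lower ones C1QA, CD68, MARCO and ITGAX. All its called members are named here, outside the rule. The proliferation list then had 15 genes lower of 32 and the monocyte markers 1 higher and 12 lower of 18, though neither list passed. Over all 12582 genes tested in both cell lines 666 were then higher and 4648 lower.

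Of 32437 probes, 91 were called, 32 higher and 59 lower, with 6969 at an unadjusted p under 0.05. In genes this was 19 higher and 41 lower. With the replicate block, whose numbers paired these samples, 265 were called (65 higher, 200 lower), and after quantile normalization 55.56% of calls were higher in place of 35.16%. The count was 9, 9 and 11894 (3405 higher, 8489 lower) without control replicates 1, 2 and 3, and 5, 5 and 6 without replicates 1, 2 and 3 in T-HESC medium.

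The series set both directions of communication side by side, so the called genes of T-HESC and U-937 were compared over 12584 genes tested in both. Averaged over hormone states, 5 genes were higher in both (4.957 if independent, 2-sided Fisher's exact test, p = 1), namely AQP9, ELOVL3, FN1, FTMT and TREM1, chosen after their values were seen. Lower in both were 20 genes (10.31 if independent, p = 0.00053, adjusted p = 0.00106, Fisher's exact test), NOP56 and HSPA1L among them. With only the effect inside the first array set, 2 were higher in both, ELOVL3 and FN1 (1.466 if independent, exact p = 0.65, adjusted p = 0.743), and 7 lower (4.23 if independent, exact p = 0.184, adjusted p = 0.245). Without control replicate 3 of U-937 the averaged numbers were 323 (275 if independent, adjusted p = 0.00032, exact test) and 1845 (1451 if independent, adjusted p = 8.96e-54, exact test), and inside the first array set 106 (81.36 if independent, adjusted p = 0.0056, exact test) and 717 (596.2 if independent, adjusted p = 1.82e-10, exact test). These tests treat genes as independent. Overlaps in opposite directions were not counted, so genes that are easily called in both cell lines are not set apart from a shared response. The direction of the U-937 calls also depended on scaling: with all its arrays 35.16% were higher, and 55.56% after quantile normalization.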

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

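The tests of the array sets and of the hormone state below were chosen only after the result was seen, as was the fit inside array sets. The effect of monocyte medium on T-HESC differed between hormone states, by a test of the difference itself (limma, interaction of monocyte medium with hormone state), for 9407 of 32479 probes (28.96%) and 3780 of 13751 genes, with 12906 probes at an unadjusted p under 0.05. Of the 100 splits drawn, the real one called 9277 of the probes with a value on every array and the highest other 8551. These splits moved hormone labels among arrays with the same medium, so they break up any difference by hormone state or array set. They cannot tell an interaction from such a difference, and no conclusion on the interaction is drawn from them. Inside array sets, where only vehicle and estradiol can be compared, limma called 0 probes (1910 at an unadjusted p under 0.05).

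The 5 genes with the smallest interaction p-values all parted the second array set from the first. MID1IP1, which promotes fatty acid synthesis (adjusted p = 1.12e-06), had a log2 effect of monocyte medium of 3.14 in vehicle, 3.16 in estradiol and -0.24 with MPA. MYL12A, a myosin light chain (adjusted p = 1.12e-06), had 3.31, 3.37 and 0.24. SARNP, an RNA export protein (adjusted p = 1.15e-06), had 2.55, 2.90 and 0.16. BRD10, a bromodomain protein (adjusted p = 1.15e-06), had -3.42, -2.98 and -0.47 on this probe. The brightest BRD10 probe had -1.31 in vehicle, and yet another was called higher there, so the probes of BRD10 do not give 1 effect of the gene. MICOS10, of the mitochondrial inner membrane (adjusted p = 1.54e-06), had 1.87, 1.79 and -0.48.

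Monocyte medium called 19187 probes in vehicle and 19041 in estradiol, both across array sets, against 6914 with MPA inside a set. A difference of RNA should be shared by the 2 probes of a gene, which was examined across the 805 genes that have 2 bright probes. Pearson's r between the probes of a pair was 0.411 for the effect with MPA (95% bootstrap interval 0.323 to 0.502). For the difference between effects r was 0.187 (0.112 to 0.255), a difference in r of -0.225 (-0.335 to -0.116). A difference between effects carries the noise of more arrays, which alone can lower r. The effects in vehicle (0.225, 0.151 to 0.306) and estradiol (0.24, 0.166 to 0.317) rest on as many arrays as the effect with MPA, and their r was lower too. The array sets may therefore be a part of the difference, of a size that these values do not give. Probe pairs still shared 18.5% of the variance of the difference, and since each hormone state lies in 1 set, that part cannot be told apart from a response of the cells without the progestin. Genes are not independent replicates, and the biological explanation, a progestin that limits the response to monocyte medium, stays open.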

How the results depend on the processing

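The alternatives with array sets and the fit of the first set alone were chosen only after the results were seen. With the array set as a block 138 calls of named genes were lost and 17 reversed, while 140 results stayed on their side. Results on their side, here and below, include genes or lists that were called neither before nor after. Quantile normalization ended 45 calls and added 7, no trend ended 41, no intensity filter 39, the arrays of the groups compared alone 22 with 14 added, median centring 4, the first set alone 1 with 5 added, the offset 4 with 4 added, and array weights 2 with 42 added. The stricter filter ended none and added 2 beside 700 on their side, and the replicate block ended none and added 18 beside 833. Leaving out 1 array ended 599 calls, added 35 and left 6815 results on their side.

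Estradiol without monocyte medium (2 probes) gave 0 with the stricter filter, which removes dim probes, 0 with the offset, 0 with only the arrays of the groups compared, 4 without trend and 4 with the replicate block. Averaged it gave 0, and 1 with array weights; with monocyte medium 0, 10 with array weights and 3 with the replicate block. MPA with estradiol without monocyte medium gave 238 probes against estradiol, 610 with array weights, 634 with the replicate block, 530 with only the arrays compared and 399 in the first set alone. Against vehicle it gave 420, and 1010, 1216, 854 (319 higher, 535 lower) and 805 (336 higher, 469 lower) in the same order. U-937 gave 91 probes, 16 without trend, 10717 with array weights, 265 with the replicate block, and 786 genes in place of 60 with the mean over probes. Where array weights raised a count, the cause was not tested, nor was that of the other changes in this paragraph.

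With the array set as a block monocyte medium averaged gave 6928 probes in place of 22918, and MPA with estradiol averaged gave 379 in place of 9741 against estradiol and 434 in place of 8780 against vehicle. By construction this block leaves only differences inside sets. The interaction inside sets gave 0 in place of 9407. Reversed with the block were MXI1 (0.47), TALDO1 (-0.0142) and ESR2 (-0.15) for monocyte medium averaged. For MPA with estradiol averaged against estradiol these were IL15 (0.0188), AURKA (-0.14), MCM6 (-0.32), SC5D (0.15), DDIT4 (-0.10), MXI1 (-0.34), TXNRD1 (0.28) and ESR2 (0.23), and against vehicle PLK1 (0.0321), SC5D (0.14), MXI1 (-0.00858), DDIT4 (-0.028), TXNRD1 (0.10) and ESR2 (0.31).

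Leaving out 1 array gave 22180 to 23011 probes for monocyte medium averaged, 16804 to 18991 in vehicle, 16923 to 19018 in estradiol and 4357 to 5247 with MPA. Estradiol gave 0 to 1 averaged, 1 to 6 without and 0 to 0 with monocyte medium. MPA with estradiol gave 8213 to 9730 averaged, 101 to 153 without and 12184 to 13806 with monocyte medium against estradiol, and 7056 to 8975, 164 to 369 and 10828 to 12420 against vehicle. The interaction gave 7404 to 9991 and U-937 5 to 11894, the last without control replicate 3.

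With an estimated correlation in place of the preset one, 17 list calls were lost and 277 list results stayed on their side. Without the filter 6 were lost and 4 added, and with quantile normalization 2 were lost and 7 added. The replicate block added 4: immediate early genes with monocyte medium averaged (0.0465), interferon and proliferation genes for MPA with estradiol against estradiol without monocyte medium (both 0.024) and oxidative stress genes for estradiol with monocyte medium (0.0354). The block changed no other list call, and no count by more than 1.5 times beyond those above. Signal near background limits the dim probes: the offset ended the call of MHENCR under estradiol (adjusted p = 0.0725).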

Other observations

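The tests of U-937 control replicate 3 and of unequal strength between replicate numbers were chosen only after the results were seen, those of scaling and of other splits before. Control replicate 3 of U-937 lay nearer the arrays with T-HESC medium (Pearson's r across probes 0.981 to 0.983) than the other controls (0.96 to 0.965). Among themselves the arrays with T-HESC medium correlated at 0.986 to 0.987, slightly more closely than with control 3. MMP1, at 2.1 and 2.0 in the other controls, was at 14.9 in control 3 and at 17.2 to 22.4 in T-HESC medium. A swap between the groups needs an array with T-HESC medium that resembles the controls, and the lowest difference in mean r of such an array was 0.0213 towards its own group, which argues against it. On a scale from the other controls (0) to T-HESC medium (1), the median position of control 3 over 1385 probes was 0.927. The arrays with T-HESC medium lay at 0.866, 0.899 and 1.06, so RNA from a culture with T-HESC medium is a candidate explanation. Not every gene went with it. Control 3 lay near the other controls in FN1 (0.226, against 3.19 to 3.75 in T-HESC medium), LTBP1 (1.51), CEACAM6 (2.62) and BRCA1 (7.47). S100A8 (2.28) lay between the groups. These genes were called with control 3 among the controls, which favours genes where it resembles them, so they do not decide the question. A control culture in another state cannot be told apart from a wrong label, since either would put the array at that position. The 275 probes called between control 3 and the arrays with T-HESC medium (limma, with the lone array assumed to vary like the others) do not separate them.

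With monocyte medium, replicates 3 and 1 differed alike in vehicle and in estradiol (Pearson's r across probes 0.81, against 0.357 without it). A difference in array scaling between replicate numbers is argued against by r after quantile normalization, 0.819. The difference followed the effect of monocyte medium measured with MPA, in other arrays (r 0.482, against 0.0705 for replicates without the medium), so medium or cultures of unequal strength may be the source. No biological explanation was tested, and genes are not independent replicates.

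Other splits of the arrays were counted on probes with a value on every array. For monocyte medium averaged the real split called 22493 probes and the highest other 20143 (1 of 100 as large), which excludes chance alone. The highest other split still parted every vehicle and estradiol array by monocyte medium. MPA with estradiol averaged called 9602 against estradiol and 8638 against vehicle, and 3 of 100 splits called as many in each, up to 10174 and 9140. These splits kept the arrays with monocyte medium parted by array set, and inside the first set the counts without monocyte medium were 238 and 420. Estradiol averaged called 0, and all 100 splits called as many, up to 2353 in a split that parted replicate numbers 1 and 3. Estradiol with monocyte medium called 0, all 10 splits as many, and the highest 4066. That split and another with 1721 both parted replicate numbers 1 and 3, which points to that structure, and with the replicate block 3 probes were called.

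With 3 arrays against 3 there are 10 splits and the share cannot go below 0.1. The real and highest other counts were 18844 and 0 for monocyte medium in vehicle, 18714 and 0 in estradiol and 6813 and 0 with MPA. For MPA with estradiol they were 235 and 1 against estradiol and 415 and 0 against vehicle without monocyte medium, and 13937 and 1, and 12728 and 0, with it. Estradiol without monocyte medium gave 1 and 1, with 2 splits as large, and U-937 gave 90 and 0.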
